A study of Homo sapiens with 4 samples.

How the data were processed

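Chromatin immunoprecipitation and sequencing (ChIP-seq) was used to map a FLAG-tagged ZNF416 protein in IMR90 cells, which are cultured human lung fibroblasts. Per the labels' protocols, the cells carried the tagged gene from a lentiviral vector and had been selected with puromycin. They were crosslinked with formaldehyde for 10 minutes, chromatin was cut with micrococcal nuclease and sonication, and FLAG-bound chromatin was pulled down with anti-FLAG beads. The libraries were read for 51 bases from both ends. The labels put 2 libraries in the ZNF416-FLAG ChIP group and 2 in the input group (sheared chromatin without the pull-down), with replicate numbers 1 and 2 in each. The protocol describes the 2 replicates as biological.

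What was analysed was 1 list of peaks for the whole series, on the hg19 build. Per the submitters' processing notes, the tools were Bowtie2, Picard, MACS2, deepTools and HOMER, named without versions or roles. Per the file headers, HOMER annotated a MACS2-style narrow peak list from which blacklisted regions had been removed. How the 2 ChIP libraries were combined, and how the input was used in the calling, are not given in the sources used here. The deposited score is a whole number per peak that the authors carried over from the peak caller's output, and its scale is not stated. It was used only to describe, rank and filter peaks within this list. Its smallest value, 13, equals 10 times −log10 of a q-value of 0.05 rounded down, which is an inference from the value alone. The list gives no read counts, so the depth of each library is unknown, and no value of single ChIP or input libraries was analysed. No spread between replicates can therefore be given for any value. Intervals of shares are exact Clopper-Pearson 95% intervals over peaks or genes, and they leave out the error of the peak calling itself. Peaks and genes are not replicates of the experiment.

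Positions, nearest transcription start sites (TSS), signed distances from the peak centre, annotation classes and overlapping repeats are those of the authors' HOMER annotation. Starts and ends are printed as deposited. Widths were taken as end minus start plus 1, because HOMER prints 1-based positions. A peak was called a promoter peak when its centre lay within 1 kb of a TSS. Each peak was credited only to the gene of its nearest TSS, so the window around a gene is cut short where another TSS is close. Of the 1142 peaks with a gene identifier, 1140 matched a gene of a RefSeq gene table for the GRCh38.p14 assembly. That table was used for names, for gene type and for the chromosome a gene lies on, and none of its coordinates were used. The gene that holds an intronic or exonic peak was found from the transcript accession of the annotation, which matched for 766 of 775 peaks. A further 3 peaks had a TSS distance and no gene name. Another 2 gene names had been turned into dates by a spreadsheet, and their gene identifiers were used.

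Before the data were examined, 22 gene lists were fixed. They cover fibroblast activation by stiff matrix, promoters used in every cell, silent genes and markers of other cell types. Each list was tested with a two-sided Fisher's exact test of genes with a promoter peak against all other of the 20052 protein-coding genes of the table, with Benjamini-Hochberg adjustment over the 22 lists. Odds ratios are conditional maximum likelihood estimates with exact 95% intervals. Median scores were compared with a two-sided permutation test of 100000 resamples, and the interval of the difference came from 2000 bootstrap draws. The comparison of scores on contigs with those on chromosomes, and the exact tests of upstream against downstream peaks, were added after the data had been seen. A test of the share of promoter peaks against the genome and a search for the ZNF416 motif had been planned, and both were left out because no genome sequence of this build was used here.

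The genes named in the text were set by a rule fixed in advance. It takes the genes of the 10 peaks with the highest score, and for each list up to 4 members with the strongest promoter peak. For a list without promoter peaks it takes up to 2 members by nearest gene at any distance. It always takes 10 genes, which are ZNF416, ACTA2, COL1A1, COL1A2, FN1, CCN2, TGFB1, PDGFRA, YAP1 and SRF. It also takes up to 5 genes with 4 or more peaks, by number of peaks, and ties there were settled by the strongest peak. One item that the rule takes is not reported here. Other genes that the closing section names were chosen after their values were seen.

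Both tests were tested on simulated data. In 100 simulations per size, 268 of the 20052 genes were drawn, with a planted excess in the extracellular matrix list of 53 genes. The planted list passed an adjusted p of 0.05 in 5% of simulations at a 3-fold weight, in 21% at 5-fold and in 71% at 10-fold. With no planted excess it passed in 0%, and 0.14 of every 100 other lists passed. For the medians, a planted shift of 5 score units between groups of 333 and 812 peaks was called in 50% of 40 simulations, one of 10 units in 97.5%, and no shift in 5%. Alternatives covered the window around the TSS, the authors' own promoter class, stricter score limits, removal of contigs, merging of neighbouring peaks and another gene background. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.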

Results

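ZNF416 is a zinc finger protein of the KRAB class, and the study asked about its part in the activation of lung fibroblasts by mechanical cues. To map where the tagged protein sits on the genome, FLAG ChIP-seq was run on IMR90 lung fibroblasts, with 2 ChIP and 2 input libraries. No FLAG pull-down from cells without the tagged protein was among these libraries. Pull-down signal that does not come from the tagged protein can therefore not be told apart here. The libraries enter here only through the authors' own peak calling. Its result is 1 list of peaks on hg19, each with a position and the authors' score, so no value has a spread between replicates.

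The list held 1386 peaks. Their median width was 145 bp (quartiles 119 and 210), and their median score was 62, within a range from 13 to 355. On assembled chromosomes lay 1080 peaks, 77.9% of the list (exact 95% interval 75.6 to 80.1). Chromosome 1 carried 111 of them, chromosome 11 carried 78, chromosome 2 carried 77 and chromosome 19 carried 76. The other 306 peaks, 22.1% (19.9 to 24.4), lay on unplaced or unlocalised contigs. A single contig assigned to chromosome 9, gl000199, carried 177 peaks, more than any chromosome. The median score was 67 on contigs and 60 on chromosomes, a difference of 7 (bootstrap 95% interval 1.5 to 15.5; two-sided permutation p = 0.0206). The resampling took single peaks as units, although neighbouring peaks of the same contig are not independent. This p and interval therefore do not measure a difference between contigs and chromosomes as groups of sequences. The difference rested on gl000199, whose median score was 87. Without it the median of the other 129 contig peaks was 55, which did not differ detectably from that of chromosomes (two-sided permutation p = 0.161).

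**Figure D1:**
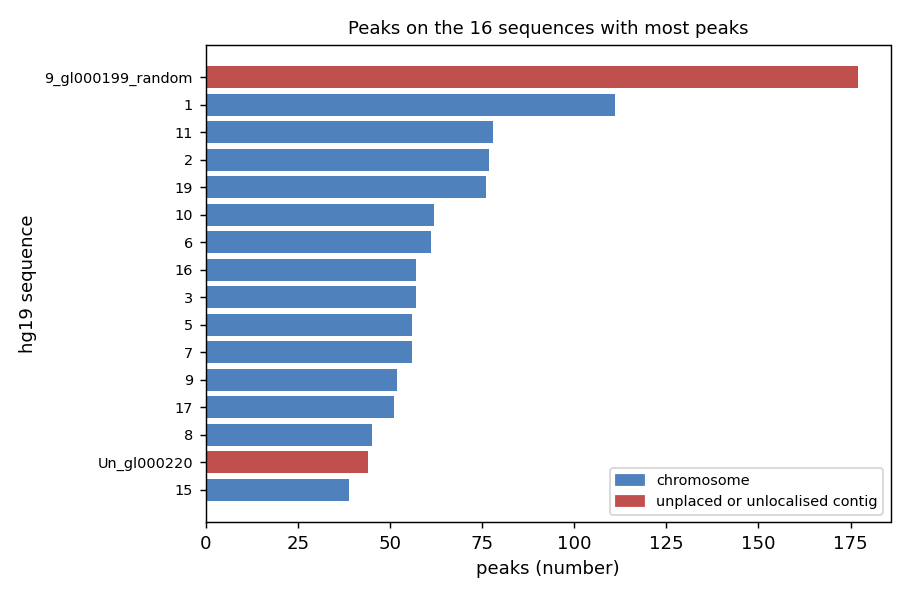
Bars give the number of peaks (horizontal axis) on the 16 hg19 sequences with most peaks, with chromosomes in blue and contigs in red. The contig gl000199 stands at 177 peaks, above chromosome 1 with 111.

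Of the 10 strongest peaks, 3 were promoter peaks, 6 lay in introns, and 6 were more than 10 kb from a TSS. The highest score, 355, belonged to a peak in intron 4 of SLC6A3, the dopamine transporter gene (chromosome 5, 1422426 to 1423100), 22792 bp downstream of the TSS. JUNB, which encodes a subunit of the AP-1 transcription factor, followed with a score of 337. Its peak lay in its only exon, 819 bp downstream of the TSS (chromosome 19, 12902613 to 12903626). A peak with a score of 334, 1292 bp wide, was centred in intron 1 of EEF1A1, a translation elongation factor gene, 318 bp downstream of the TSS (chromosome 6, 74229792 to 74231083). The peak upstream of ARID5B, a gene for a DNA-binding protein, scored 319 and lay 357 bp from the TSS (chromosome 10, 63661025 to 63661178).

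The other 6 of these peaks lay more than 1 kb from a TSS. A peak of score 321 lay in an intergenic stretch 42012 bp upstream of the long non-coding RNA gene SLC8A1-AS1 (chromosome 2, 40102511 to 40103013). Intron 1 of BACH2, a transcriptional repressor gene, held a peak of score 310 (chromosome 6, 90993798 to 90994067). The peak nearest to KCTD15 scored 285 and lay in intron 3 of CHST8 (chromosome 19, 34258971 to 34259104), 28738 bp upstream of the KCTD15 TSS. The peak nearest to the small nucleolar RNA gene SNORA30 scored 262 and lay in intron 15 of SRCAP, a chromatin remodeller gene (chromosome 16, 30724510 to 30725126). Intron 1 of MYOF, the gene of the membrane repair protein myoferlin, held a peak of score 254 on an Alu repeat (chromosome 10, 95226338 to 95226709). An intergenic peak of score 253 lay 18335 bp from the TSS of TICAM1, a Toll-like receptor adaptor gene (chromosome 19, 4813289 to 4813550).

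A TSS distance was given for 1145 peaks, and the other 241 lay on contigs with no annotated TSS. Promoter peaks numbered 333, or 29.1% of those with a distance (exact 95% interval 26.5 to 31.8). A further 276 peaks (24.1%) lay over 1 to 10 kb away, 463 (40.4%) over 10 to 100 kb, and 73 (6.38%) beyond 100 kb. Among the promoter peaks, 206 lay downstream of the TSS and 127 upstream, so 61.9% were downstream (56.4 to 67.1; two-sided exact binomial test against equal numbers, p = 1.76e-05). The excess was not limited to promoters, since 57.6% of the 812 peaks beyond 1 kb were also downstream (54.2 to 61.1), and these shares did not differ detectably (two-sided Fisher's exact p = 0.209). Random positions need not split evenly around their nearest TSS, and neighbouring peaks are not independent. The split of random positions was not measured, so no preference of the protein for the downstream side follows. The median distance of promoter peaks was 301 bp. By annotation class, 467 peaks were intronic (40.8%), 370 intergenic (32.3%) and 188 in the promoter class (16.4%). The share near a TSS was not compared with the genome, and it follows the window, with 20.9% within 500 bp and 42.9% within 5 kb.

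**Figure D2:**
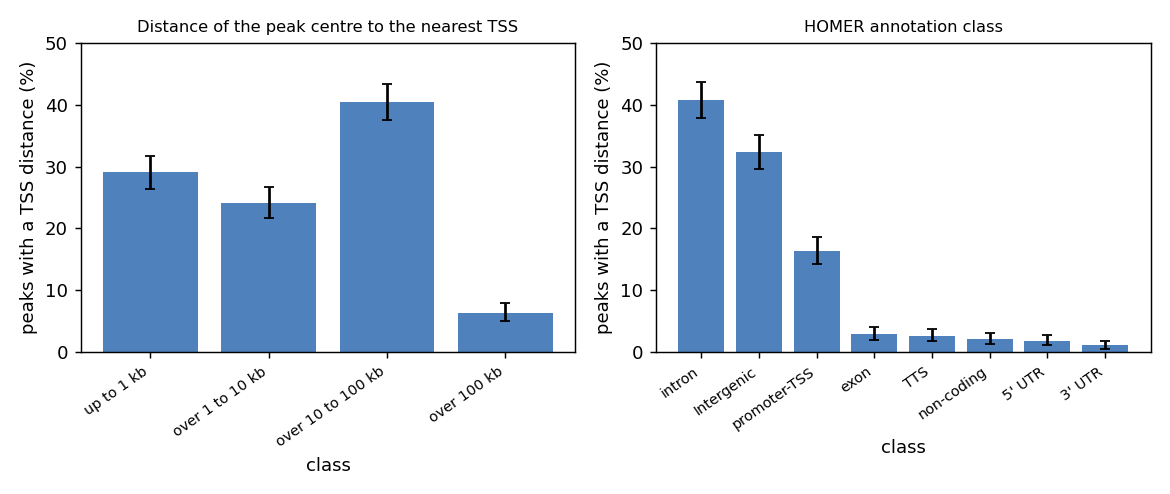
Bars give the percentage of the 1145 peaks with a TSS distance, by distance to the nearest TSS (left) and by annotation class (right), with exact 95% intervals as error bars. Peaks over 10 to 100 kb away (40.4%) and intronic peaks (40.8%) form the largest class in each panel.

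Promoter peaks were not detectably stronger than the others. Their median score was 61, against 58 for the 812 peaks farther from a TSS, a difference of 3 (bootstrap 95% interval −4 to 6; two-sided permutation p = 0.391).

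The promoter peaks fell at 313 genes, of which 268 were protein-coding, 1.34% of the 20052 protein-coding genes. Several genes of fibroblast activation were among them. ACTA2, the smooth muscle actin gene used as a marker of myofibroblasts, had 1 peak with a score of 75 (chromosome 10, 90750910 to 90751062). It lay 168 bp downstream of the nearest ACTA2 TSS and was annotated to the promoter of a FAS transcript. The distance to other ACTA2 start sites was not analysed, so the peak need not lie at the promoter that myofibroblasts use. ACTA2 counts as a promoter hit in the lists below through this peak alone. Whether the peak belongs to ACTA2 or to FAS was not tested. The peak at the matrix protein gene TGFBI scored 109 and lay 195 bp upstream of the TSS (chromosome 5, 135364412 to 135364553). EFEMP2, an elastic fibre gene, had a peak of score 67 in intron 1 (chromosome 11, 65639799 to 65640075). LOXL2, which encodes a collagen crosslinking enzyme, had one of score 56 that lay 280 bp upstream (chromosome 8, 23261841 to 23261985). FLNC, an actin crosslinker gene, had a peak of score 62 at 994 bp upstream (chromosome 7, 128469373 to 128469560).

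None of the lists for fibroblast activation passed Fisher's exact test, and at a raw p under 0.05 only 2 of the 22 lists stood out, the zinc finger and p53 lists described below. Extracellular matrix genes had a promoter peak in 2 of 53 cases (TGFBI and EFEMP2; odds ratio 2.91, Fisher's exact adjusted p = 0.579), and crosslinking and remodelling genes in 1 of 38 (LOXL2; adjusted p = 0.979). Contractile and actin genes had 2 of 52 (ACTA2 and FLNC; odds ratio 2.97, Fisher's exact adjusted p = 0.579). Integrin and focal adhesion genes had 2 of 42, which were the Src-family kinase gene FYN with a score of 142 and the hyaluronan receptor gene CD44 with a score of 60 (Fisher's exact adjusted p = 0.579). Targets of SRF and its cofactor MRTF had 2 of 35, JUNB and ACTA2 (odds ratio 4.50, Fisher's exact adjusted p = 0.579). In the list for TGF-beta and BMP signalling, 1 of 44 genes had a promoter peak, the co-receptor gene TGFBR3 with a score of 44 (Fisher's exact adjusted p = 0.984). Regulators of lung mesenchyme had 1 of 37, the transcription factor gene OSR2 with a score of 94 (Fisher's exact adjusted p = 0.979). Cell cycle genes had 1 of 63, the cyclin-dependent kinase inhibitor gene CDKN2C with a score of 91 (Fisher's exact adjusted p = 1).

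Among targets of YAP and TEAD, 0 of 35 genes had a promoter peak (upper limit of the exact interval 10.0%), and the strongest peak nearest to such a gene was that in intron 1 of MYOF. Growth factors and receptors had 0 of 49 (upper limit 7.25%). The strongest peaks nearest to such genes were a peak of score 60 that lay 59728 bp upstream of IGF1 and peaks of score 59 in intron 2 of CTF1 and nearest to EGFR, which were tied. These lists are small, and with simulated data a 5-fold excess in a list of 53 genes passed the test in 21% of runs.

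KRAB-type zinc finger genes were the only one of the 22 lists to pass. Promoter peaks lay at 5 of 68 genes, 7.35% (exact interval 2.43 to 16.3), against 1.32% of other protein-coding genes (odds ratio 5.95, 1.85 to 14.8; Fisher's exact adjusted p = 0.0474). All 5 genes lie on chromosome 19. ZNF181 had a peak of score 121 in its first exon (35225195 to 35225402), and ZNF790 one of score 103 at 179 bp upstream (37329407 to 37329530). ZNF260 had a score of 63 at 290 bp upstream (37019410 to 37019516) and ZNF20 a score of 31 at 809 bp upstream (12251919 to 12252030). The fifth, ZNF274, had a score of 21, and it falls outside the naming rule and was named because the count is small. The Fisher's exact adjusted p rose to 0.0883 with a 5 kb window (odds ratio 4.31) and to 0.113 with the nearest gene at any distance (odds ratio 2.56). It rose to 0.233 with the stronger peaks only (3 of 68 genes, odds ratio 6.68). Against genes nearest to a peak it rose to 0.585 (5 of 6 genes, odds ratio 8.82, 0.979 to 419). Genes of the p53 and stress response had 3 of 40, with a raw p of 0.0162 and an adjusted p of 0.178. These were TP53I3 with a score of 107, NQO1 with 74 and the death receptor gene FAS with 17.

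No comparator list passed the test. Ribosomal protein genes had 1 of 75 (RPL32, score 166; Fisher's exact adjusted p = 1) and general housekeeping genes 2 of 59 (EEF1A1 with a score of 334 and GAPDH with 35; adjusted p = 0.586). Respiratory chain genes had 0 of 44 and histone genes 0 of 18. Developmental transcription factor genes had 1 of 60 (BARHL1, score 44). Markers of epithelial cells (0 of 40), endothelial cells (0 of 30), immune cells (0 of 40) and neurons (0 of 38) and olfactory receptor genes (0 of 51) had no promoter peak. The upper limits of the exact intervals for these 5 lists ran from 6.98% to 11.6%. At any distance, peaks were nearest to VWF (score 63), CSF1R (47), ZAP70 (22), TUBB3 (121) and ELAVL3 (33).

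**Figure D3:**
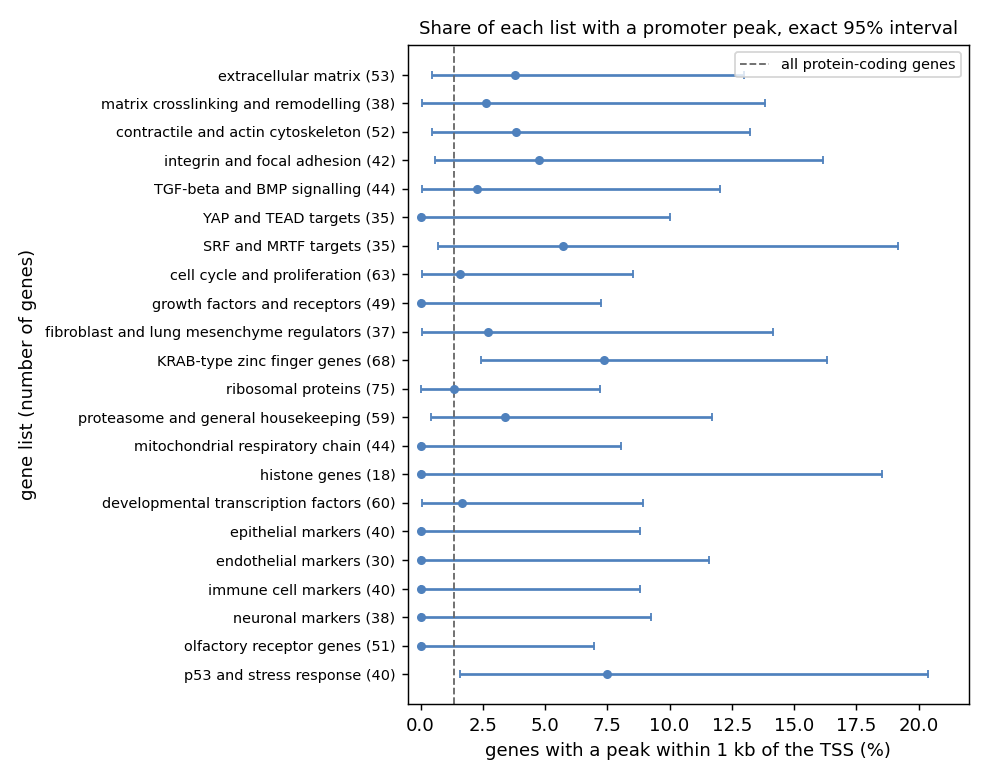
Points give the percentage of genes in each of 22 lists (rows, with the number of genes) that had a peak within 1 kb of the TSS, and bars give exact 95% intervals. The dashed line marks all protein-coding genes at 1.34%, and the KRAB-type zinc finger list stands at 7.35%.

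Of the 10 genes chosen in advance as central to fibroblast activation or to ZNF416 itself, 8 were nearest to no peak. These were ZNF416, the collagen genes COL1A1 and COL1A2, the fibronectin gene FN1, TGFB1, PDGFRA, YAP1 and SRF. Beside ACTA2, only CCN2, a matricellular growth factor gene, was nearest to a peak, with a score of 19 at 31524 bp upstream of the TSS (chromosome 6, 132303983 to 132304089).

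Genes with 4 or more peaks numbered 8. On contig gl000220, which carries ribosomal RNA genes, MIR6724-2 was nearest to 24 peaks and RNA28SN4 to 16, with highest scores of 85 and 66. LOC100505874 was nearest to 10 peaks on contig gl000224. The 4 peaks of IFITM3, an interferon-induced membrane protein gene, spanned chromosome 11 from 321043 to 322619, with 2 within 1 kb of the TSS and a highest score of 104. SBNO2 had 4 peaks in intron 1 (chromosome 19, 1154703 to 1169468), the strongest with a score of 84. IFITM3 and SBNO2 were taken by score from 5 genes with 4 peaks each.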

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

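The counts of missing peak numbers in this part were chosen before they were seen, and their test over whole sequences was chosen after. The comparisons of MLT2B peaks were chosen after the peaks had been counted. The test of peak spacing was also chosen then, and its criterion was changed and widened to all contigs with 4 or more satellite peaks after its values had been seen.

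Contigs without an annotated TSS carried 241 peaks, with a median score of 78. Peaks centred on alpha satellite, the repeat of human centromeres, numbered 205, and those on beta satellite numbered 27. All of these lay on contigs and 0 on assembled chromosomes, and all 177 peaks of gl000199 were centred on alpha satellite. They are therefore not read here as binding at centromeres. On contig gl000220, which carries ribosomal RNA genes, there were 44 peaks, and the report counts peaks there by nearest gene. MLT2B elements, long terminal repeats of the ERVL family, held 26 peaks on 13 chromosomes, and these also have a nearest gene. The gene list and promoter tests do not use repeat annotation, which is why these counts stand here. No control value for the same sequence was analysed, so enrichment over input was not tested for them.

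For the satellite peaks, a first explanation is that the removal of blacklisted regions did not reach the contigs. The peak caller numbers its peaks in order, and between the first and last peak of each of 11 contigs 0% of 304 numbers were missing, against a mean of 24.1% over 23 chromosomes (two-sided permutation of whole sequences, p = 0.00274). All 11 contigs had 0 missing, against 3 of 23 chromosomes, so the groups differed in the direction that this explanation predicted. The missing numbers were unevenly spread, with 348 of 515 on 5 chromosomes, while 4 other chromosomes had only 1 missing. A lack of missing numbers is thus not particular to contigs. The list does not tell why a number is missing, so this explanation stays open. A second is that reads from many satellite copies pile up on the few copies in the assembly. The share of the span between the first and last peak that lay within 1 kb of a peak was 95.01% on gl000199, 100% on gl000226 and 100% on gl000228, but 27.7% on gl000225, 8.10% on gl000216 and 5.13% on gl000208. The span was 145731 bp on gl000199 and 14902 bp on gl000226. On gl000228 it was only 2263 bp, so a share near 100% followed there from the 1 kb margin itself. The contigs differed, and neither their satellite content nor the input signal on them was analysed here, so binding and read pile-up cannot be told apart, and no biological explanation was tested.

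The 26 peaks in MLT2B elements made up 61.9% of the 42 peaks in ERVL repeats (exact 95% interval 45.6 to 76.4), and 0 lay within 1 kb of a TSS. The strongest, with scores of 117 and 111, were nearest to LINC00355 (chromosome 13, 64863541 to 64863780) and to SPRY1, a growth factor signalling inhibitor gene (chromosome 4, 124283198 to 124283683). Their median score was 52.5, against 58 for 184 peaks on other repeats of assembled chromosomes (two-sided permutation p = 0.55). Their median width was 176 bp against 138 bp (two-sided permutation p = 0.0201). How many MLT2B elements the genome holds was not used here, so no excess over chance was tested.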

How the results depend on the processing

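The share of promoter peaks over all 1386 peaks, the lists on chromosomes 1 to 22 and X, the scores without gl000199 and the addition of the cell cycle list were chosen after seeing the data. The list held 698 peaks at or above the median score and 357 with a score of 87 or more, by construction. Keeping only chromosomes 1 to 22 and X, or merging neighbours, kept the count within 1.5 times, at 1079 and 1106 peaks. The promoter share moved with its definition, to 20.9% within 500 bp, 42.9% within 5 kb, 16.4% by the authors' promoter class and 24.03% over all peaks. It was 30.6% among peaks at or above the median score and 29.2% among those at 87 or more. The difference in median score lay between 1 and 3 and never passed the permutation test. The score difference between contigs and chromosomes turned from 7 to −5 without gl000199, the contig with most peaks. The number of lists that passed was 1 at any distance and 1 on chromosomes 1 to 22 and X. It was 0 with a 5 kb window, 0 with the stronger peaks and 0 against genes nearest to a peak, where fewer genes were tested. The odds ratio of the zinc finger list was 4.31, 6.68 and 8.82 in these settings, against 5.95 in the main run. The exact interval of this odds ratio stayed above 1 within 5 kb (1.35 to 10.7) and with the stronger peaks (1.33 to 20.8). It ran from 0.979 to 419 against genes nearest to a peak. At any distance the odds ratio of the zinc finger list fell to 2.56 (0.902 to 5.92), and its call was lost too. These settings draw on largely the same few genes, so they are not independent of the main run. The lost calls therefore do not show whether its excess persisted or went away. The list that passed at any distance was that of SRF and MRTF targets, not the zinc finger list.

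Odds ratios of single lists crossed 1 as follows, none with an adjusted p under 0.05, and the cause was not tested. At any distance they were 3.41 for YAP and TEAD targets, 3.69 for growth factors, 0.424 for cell cycle, 0.923 for housekeeping, 0.445 for developmental factors, 1.39 for immune and 1.46 for neuronal markers. Within 5 kb they were 0.867 for cell cycle, 0.911 for developmental factors and 2.999 for neuronal markers. With the stronger peaks they were 0 for crosslinking, 0 for TGF-beta and 0 for developmental factors, and 1.93 for ribosomal proteins. Against genes nearest to a peak they were 0.869 for extracellular matrix, 0.578 for crosslinking, 0.433 for TGF-beta, 0.869 for SRF targets, 0.869 for mesenchyme regulators and 1.74 for ribosomal proteins. In that background no finite odds ratio could be had for 3 lists whose members nearest to a peak all had promoter peaks, and none for lists with no member left. Not run were the motif search with its alternatives and another strength column, since neither a genome nor such a column was used here. No paired analysis was possible because the peak list has no values for single libraries. For the same reason no replicate could be left out, and what depth limits is unknown.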

Other observations

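The tests of joined lists and of the wider zinc finger family were chosen after the counts per list had been seen. The SRF and MRTF list at any distance was planned, and the comparison within chromosome 19 was chosen before its result was seen.

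Of all protein-coding genes, 734 were nearest to a peak at any distance and 268 had one within 1 kb, and for the activation genes these numbers were 39 and 10. At any distance, 5 TGF-beta and BMP genes were nearest to a peak, among them the ubiquitin ligase gene SMURF2 with a score of 204 at 2524 bp upstream (chromosome 17, 62660883 to 62661016), the endoglin gene ENG with 85 in intron 2, and SKI with 76 in intron 1. Among growth factors and receptors, 6 of 49 genes were nearest to a peak. Beside IGF1 and CTF1 these were EGFR (score 59, 23178 bp from the TSS), PDGFB (53, 32796 bp), PDGFA (30, 48033 bp) and KITLG (27, 213048 bp). Matrix genes at any distance included IGFBP7 (score 67, 9016 bp from the TSS), COL16A1 (57, 2514 bp), NID1 (53, 32154 bp) and COL5A1 (30, 78199 bp). The SRF and MRTF list passed the test at any distance, with 6 of 35 genes (17.1%; odds ratio 5.48, Fisher's exact adjusted p = 0.034). Beside JUNB and ACTA2 it held CNN1 (score 57, 2834 bp from the TSS), ATF3 (38, 8563 bp), FLNA (32, 1556 bp) and CCN2 (19, 31524 bp).

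The 9 lists joined as activation genes were those of extracellular matrix, crosslinking and remodelling, contractile, integrin and focal adhesion, TGF-beta and BMP, YAP and TEAD, SRF and MRTF, growth factor, and mesenchyme regulator genes. Of their 367 genes, 39 were nearest to a peak, 10.6% (exact 95% interval 7.67 to 14.2), against 3.53% of other protein-coding genes (odds ratio 3.25, 2.25 to 4.58; two-sided Fisher's exact p = 2.67e-09). The cell cycle list was left out of the joined lists, and with it 40 of 430 genes were nearest to a peak (odds ratio 2.80, 1.95 to 3.92; two-sided Fisher's exact p = 7.04e-08). One explanation is that genes with wide intergenic surroundings are nearest to more peaks. Within 5 kb, 16 of the 367 genes had a peak (odds ratio 2.52, 1.41 to 4.21; two-sided Fisher's exact p = 0.00124), but each peak is credited to its nearest TSS there too, and gene spacing was not measured, so this explanation stays open. Whether peaks lie near any gene in use cannot be told apart with these counts, since within 5 kb 3 of 177 ribosomal, housekeeping and respiratory genes had a peak (two-sided Fisher's exact p = 0.138 against activation genes).

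For the same comparison at any distance, ribosomal, housekeeping and respiratory genes gave 4 of 177 (2.26%; two-sided Fisher's exact p = 0.000319 against activation genes). Developmental and neuronal genes gave 3 of 98 (3.06%; Fisher's exact p = 0.0172), and markers of other cell types 5 of 148 (3.38%; Fisher's exact p = 0.00813). In the fixed windows, activation genes differed detectably from no comparator set. Within 5 kb Fisher's exact p was 0.776 against developmental and neuronal genes and 0.114 against markers of other cell types. Within 1 kb it was 0.472 and 0.0698 against these, and 0.562 against ribosomal, housekeeping and respiratory genes. High shares were not limited to activation genes. At any distance the p53 and stress response list gave 5 of 40 (12.5%) and the KRAB-type zinc finger list 6 of 68 (8.82%). ATF3 is on both the p53 list and the SRF and MRTF list. Within 1 kb, activation genes had 10 of 367 (2.72%; odds ratio 2.11, 0.991 to 3.99; Fisher's exact p = 0.0332).

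The zinc finger result was weighed in the same way. Over all 566 protein-coding genes with a zinc finger family symbol, 12 had a promoter peak (2.12%), an odds ratio of 1.63 with an exact 95% interval of 0.825 to 2.92. The 498 genes outside the list of 68 had 7 (1.41%), so the excess was not seen across genes with such symbols. The choice of the 68 genes may account for the excess. The wider set was defined by symbol and not by a KRAB domain, so it cannot show whether other KRAB-type genes share the excess. A general excess of promoter peaks on chromosome 19 was argued against, since 5 of 59 list members there had one (8.47%), against 19 of 1392 other genes of the chromosome (1.36%; two-sided Fisher's exact p = 0.0022).

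Among Alu repeats, which held 76 peaks, the older AluJ elements held 39 (51.3%; exact 95% interval 39.6 to 63.0), AluS elements 30 (39.5%) and the younger AluY elements 6 (7.89%; 2.95 to 16.4). How many copies of each the genome holds was not used.

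The authors' deposited table also holds tallies, with 1194 peaks by annotation class and 1148 by distance, where the listed peaks give 1145. The authors' deposited table counts 74 exonic and 477 intronic peaks, against 33 and 467 listed. The promoter class numbered 188 in both the list and the authors' deposited table.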
